A study of Homo sapiens with 8 samples.

How the data were processed

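Hepatic stellate cells are the liver cells that turn into contractile, matrix-producing myofibroblasts in fibrosis, and transforming growth factor beta (TGFβ) is a main driver of that change. The series holds 8 Illumina HumanHT-12 V4 arrays of human stellate cells, 1 array for each of 8 conditions. In the inhibitor arm the cells received the solvent DMSO or C646, a small molecule that inhibits the acetyltransferase activity of p300 and of its relative CBP. In the shRNA arm they carried a control short hairpin RNA or one against p300, the product of EP300. Each of these 4 backgrounds was cultured without or with TGFβ for 24 h.

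Per the labels' protocols, cells were grown in DMEM with penicillin and streptomycin, RNA was extracted with Trizol and treated with DNase I, its quality was checked on a Bioanalyser, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. The dose of C646 and of TGFβ, the donor or source of the cells, the shRNA vector, the extent of the knockdown and the authors' processing and normalization are not given in the sources used here. A paper on the series and any protein or chromatin measurements were not used here.

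The deposited values are read here as probe intensity on a linear scale. The table holds 47323 probes for each array. Values run from 81.1 to 24500, the median of an array lies between 107 and 111, and the 99th percentile between 4700 and 5800, so most probes sit at a background that was not subtracted, and a difference between dim genes is compressed. Summed intensity ran from 15064224 (p300 shRNA) to 17273852 (DMSO + TGFβ). The sorted values of the arrays are not identical. After the normalization and filter described next, Pearson's r of log2 values between pairs of arrays, across 14896 genes, was 0.945 to 0.990.

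Values under 16 were set to 16, the 8 arrays were quantile normalized together on the linear scale, and log2 was taken. A probe was kept if it reached its array's median in at least 2 of the 8 arrays, which 29907 did. Gene symbols came from the array's annotation table. Of all probes 30113 carried 1 symbol, 8 several and 17202 none; probes with several or no symbols were left out of the gene analysis, as were 144 probes of XIST and Y-linked genes. 20548 named probes passed the filter. For 4175 genes with more than 1 such probe the brightest was used, which gave 14896 genes.

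No condition has a replicate, so a difference between 2 single arrays has no error and is given as a value only. Tests treat matched pairs as repeats. 6 limma fits were planned. They cover TGFβ over all 4 backgrounds and p300 loss (C646 or p300 shRNA) over all 4 pairs, with 3 residual degrees of freedom. With 2 residual degrees of freedom, they cover TGFβ in the 2 control backgrounds, p300 loss with TGFβ, p300 loss without TGFβ, and the interaction of p300 loss with TGFβ. Each fit had the matched pair as a block. 3 further results were chosen after seeing the data, because the arms differed: C646 against DMSO, p300 shRNA against control shRNA, each over the pairs without and with TGFβ, and the difference between these effects. They rest on the same model of all 8 arrays, with 2 residual degrees of freedom shared by both arms. limma 3.58.1 in R 4.3.3 was used with eBayes and a trend, and Benjamini-Hochberg adjustment over the 14896 genes. A gene was called at an adjusted p under 0.05. These p-values measure only the spread between these 8 arrays, which may be technical, and not variation between donors or cultures.

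21 gene lists with 435 genes in all were fixed in advance. Most are described with the comparisons in which they moved. For a fit, the calls in a list are given over all genes and adjusted over the list alone, and camera compares the list with other genes, with its preset correlation of 0.01 and with an estimated correlation, adjusted over the 21 lists. With an estimated correlation camera has only the residual degrees of freedom of the fit, so hardly any list could pass. For 8 single pairs and for the arms set against each other, the median of a list is set beside 10000 random lists of the same size matched on mean level in 20 bins. Genes changed 2-fold by TGFβ in one arm's control pair were followed in the other arm, which shares no array with the selection.

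Named genes follow a rule: EP300 and CREBBP; up to 10 genes per direction that differ the same way in both arms, ranked by the smaller difference; up to 5 per direction for each p300-loss pair and for each fit with calls; and up to 4 members of a list. For the 3 added results, list members are the called ones with the largest changes, a choice made after their values were seen. "Rose" and "fell" are used of genes that passed a limma test. The lists, filters, fits, thresholds and this rule were chosen before the data were examined.

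The alternatives were the values as deposited, median centring, no filter, a filter at the 70th percentile, the mean of a gene's probes, log2 of the value plus 50, eBayes without a trend, ordinary least squares, other blocks, leaving out each array in turn, a 1.5-fold threshold and the 100 most changed genes for selection. Subtracting each array's 25th percentile before normalization, and TGFβ as an additive term in the added fits, were chosen after seeing the data. The fits were tested on simulated data of 14896 genes with known changes. At a log2 change of 1 the planned fits recovered 92.5% to 100% of changed genes, and at 0.5 between 55.2% (interaction) and 97% (TGFβ over 4 backgrounds). The simulated noise was normal with each gene's moderated variance, and changes were put in genes drawn at random. These shares can therefore be too high for the real arrays. In the real fit of p300 loss with TGFβ, KANK4 at -1.68 had a limma adjusted p of 0.124. A count of 0 thus does not show that no gene changed 2-fold. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.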

Results

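EP300, the gene for p300, was only modestly lower in the cells that carried its hairpin. Its intensity was 225 with p300 shRNA against 293 with control shRNA, and 182 against 226 when TGFβ was added, or 77.1% and 81.6% of the control level (log2 differences of -0.37 and -0.29). Over both pairs its limma adjusted p was 0.0739, so the difference did not pass the test. TGFβ went with EP300 differences of like size, -0.38 in control shRNA and -0.30 in p300 shRNA cells, and -0.24 in DMSO and -0.12 in C646 cells. The hairpin differences lay at percentiles 8.27 and 9.61 of all genes, so these arrays do not establish a knockdown at the RNA level. The term p300 loss names the treatments, C646 or p300 shRNA, and not a measured loss. C646 acts on the protein, and EP300 was at 275 against 262 in DMSO, and at 248 against 220 with TGFβ. CREBBP, which encodes the related acetyltransferase CBP, stood at 509 against 610 with p300 shRNA and at 482 against 636 when TGFβ was added; with C646 it was at 789 against 823 and, with TGFβ, higher, at 898 against 688. The EP300 probe reads 182 to 293, and array medians are 107 to 111, so background is a large share of its signal and compresses its differences. With the background subtracted, an alternative chosen after seeing the data, the EP300 differences with p300 shRNA were -0.63 and -0.60.

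**Figure D1:**
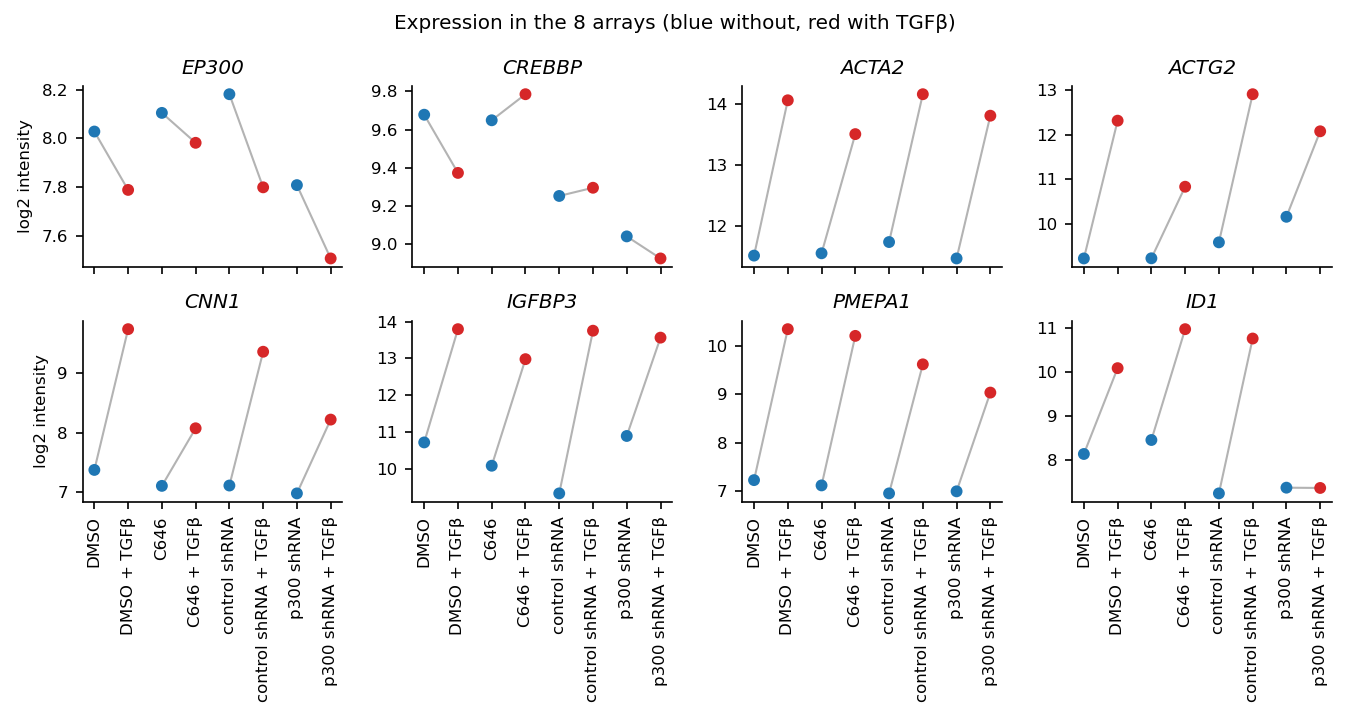
Log2 intensity (vertical axes, each with its own range) of 8 genes in the 8 arrays (horizontal axes), 1 point per array, blue without and red with TGFβ, with lines joining the arrays of a background. ACTA2 is higher with TGFβ in all 4 backgrounds, and EP300 is lowest, at 7.51, in p300 shRNA cells with TGFβ.

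With TGFβ, 18 of 24 contractile and cytoskeletal genes and 16 of 32 collagens and matrix proteins rose in the control backgrounds; for both lists camera gave adjusted p = 0.294 with an estimated correlation. In DMSO and control shRNA cells ACTA2 (smooth muscle actin, the usual mark of an activated stellate cell) rose 5.60-fold, ACTG2 (enteric smooth muscle actin) 9.29-fold, CNN1 (calponin) 4.94-fold and TAGLN (transgelin) 3.67-fold. IGFBP3, which binds insulin-like growth factors, rose 13.4-fold. KANK4, a regulator of the cytoskeleton, rose at least 13.0-fold, since without TGFβ it read 113 in DMSO and 100 in control shRNA cells, at the array medians of 109 and 108. PDGFD, a platelet-derived growth factor, fell by 2.09 on the log2 scale, and PPARG, the nuclear receptor of the quiescent, fat-storing state, by 1.52. By limma 770 genes rose and 797 fell, 1567 of 14896, and 139 and 93 of them by at least 2-fold.

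Ranked by the smaller of their changes in the control backgrounds, other genes followed. XYLT1, which starts the sugar chains of proteoglycans, had a log2 change of 3.03 (SE 0.14, adjusted p 1.21e-06), ACTG2 3.22 (SE 0.13, 9.63e-07) and ACTA2 2.49 (SE 0.12, 1.63e-06). C5orf46 (2.71), PMEPA1, a feedback inhibitor of TGFβ signalling (2.89), NUAK1, a kinase of the AMPK family (2.56), BHLHE40, a transcriptional repressor (2.45), and HBEGF, a ligand of the EGF receptor (3.07), also rose in both. Without TGFβ, C5orf46, PMEPA1 and HBEGF read near the background (log2 6.70, 6.95 and 6.91 in control shRNA cells), so their changes are lower bounds. On the other side were COLEC12, a scavenger receptor (-2.22, SE 0.13, adjusted p 3.55e-06), CLDN11, a tight junction protein (-2.72), CEMIP, which takes part in hyaluronan breakdown (-2.63), SPRY1, an inhibitor of receptor tyrosine kinase signalling (-2.20), CCN3 (-2.10) and SLC7A14 (-2.03). TGFBR3, the TGFβ co-receptor betaglycan (-1.86), PTGIS, the prostacyclin synthase (-1.86), GAS1 (-1.80) and NTN4 (-1.70), a netrin, fell as well. Adjusted p of these genes lay between 9.63e-07 and 0.000154. CCN3 read 129 with TGFβ in DMSO cells, against an array median of 111, so background compresses its fall.

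**Figure D2:**
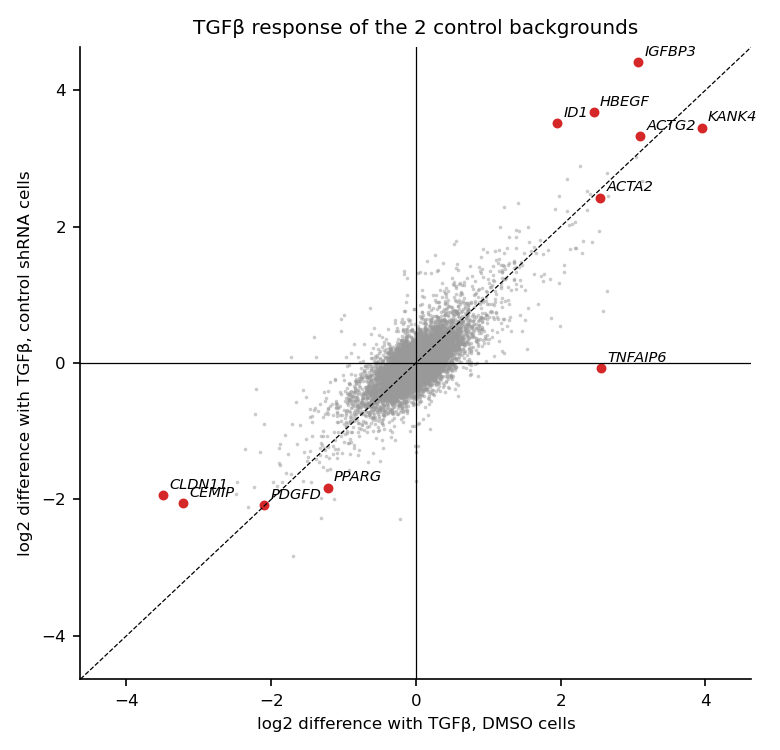
Log2 difference with TGFβ in DMSO cells (horizontal) and in control shRNA cells (vertical), 1 point per gene for 14896 genes, with named genes in red and equality dashed. Across genes r is 0.742, with IGFBP3 and KANK4 far up in both and TNFAIP6 high in DMSO cells alone (2.56 against -0.07).

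Of 24 contractile and cytoskeletal genes 18 rose and none fell, or 21 and 0 adjusted over the list alone. Of 32 collagens and matrix proteins 16 rose, among them COMP (1.95), elastin (ELN, 1.76), tenascin C (TNC, 1.55) and versican (VCAN, 1.53), and 3 fell (19 and 3 adjusted over the list alone). Of 27 TGFβ and SMAD targets 17 rose and 1 fell (17 and 2 adjusted over the list alone), with ID1, an inhibitor of differentiation (2.74), and the oxidase NOX4 (2.58) beside PMEPA1 (2.89). Of 24 matrix crosslinking and remodelling enzymes 7 rose and 1 fell (11 and 1 adjusted over the list alone), with the metalloproteinase ADAM19 (2.10), the collagen lysyl hydroxylase PLOD2 (1.504), MMP10 (1.10) and ADAM12 (0.89). By camera these lists were higher than other genes, at adjusted p of 1.08e-20, 1.95e-09, 3.08e-17 and 7e-06 in that order; each had adjusted p = 0.294 with an estimated correlation.

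Genes of the amino acid and endoplasmic reticulum stress response were also higher: 9 of 22 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p 3.82e-08, adjusted p = 0.341 with an estimated correlation). They included the amino acid transporter SLC7A5 (1.75), the transcription factor ATF3 (1.47), TRIB3 (1.22) and DNAJB9 (0.99). Of 22 YAP and TAZ targets 7 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p 0.000526, adjusted p = 0.665 with an estimated correlation), with IGFBP3, GADD45B (2.40), CCN2 (1.76) and CCN1 (1.01). Of 8 epithelial and cholangiocyte markers KRT7 (0.93) and SOX9 (0.70) rose, the latter a transcription factor that activated stellate cells also express (3 and 0 adjusted over the list alone; camera adjusted p 0.012, adjusted p = 0.341 with an estimated correlation).

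Of 12 quiescent stellate cell genes 5 fell and none rose, over all genes and adjusted over the list alone (camera adjusted p 0.00152, adjusted p = 0.294 with an estimated correlation): beside PPARG there were the transcription factor HAND2 (-0.98), PLIN2, a coat protein of lipid droplets (-0.89), and cytoglobin (CYGB, -0.72). Of 20 inflammatory and NF-kB targets 3 fell, VCAM1 (-0.95), CCL2 (-0.73) and PTGS2 (-0.67), and none rose, over all genes and adjusted over the list alone (camera adjusted p 0.0297, adjusted p = 0.768 with an estimated correlation). The same list has a far higher level in the control shRNA than in the DMSO cells (median log2 difference 1.61 without and 0.82 with TGFβ), and its median response to TGFβ was -0.31 and 0.02 in these backgrounds. 22 lysine acetyltransferases and deacetylases had no called member and a median of -0.09 (camera adjusted p 0.049, adjusted p = 0.341 with an estimated correlation).

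Other lists went both ways or held few calls. Of 23 secreted growth factors and cytokines 5 rose and 6 fell (10 and 7 adjusted over the list alone), with PDGFC (1.26) and HBEGF (3.07) up and PDGFD (-2.09) and the chemokine CXCL12 (-1.65) down. Of 15 NRF2 and oxidative stress genes 2 rose and 4 fell, with HMOX1 (0.56) against AKR1C2 (-1.79), AKR1C3 (-1.37) and NQO1 (-0.52). The mesenchymal list had 4 of 14 lower, among them PDGFRA (-1.05), LUM (-0.86) and S100A4 (-0.65). Of the p53 list 1 of 18 rose and 3 fell, CCNG1 by the most (-0.66). Heat shock genes (HSPB1 0.86, HSPA1B -0.67) and interferon-stimulated genes (XAF1 0.72, IFITM1 -0.73) had 1 called in each direction, and cholesterol synthesis had only LSS (-1.17). None of 29 cell cycle genes, 9 hepatocyte, 3 endothelial and 9 leukocyte markers was called by limma. Over the whole array 3549 genes had an unadjusted p under 0.05, where chance gives 745.

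The count of TGFβ-changed genes in controls depends on the processing and on how the spread is estimated. It was 447 with the arm as the only block, and 0 by ordinary least squares. With the background subtracted, which also lets every probe through the filter, it was 1. It was 531 without the DMSO array, 530 without DMSO + TGFβ, 666 without control shRNA and 660 without control shRNA + TGFβ.

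Over all 4 backgrounds 1130 genes rose and 1187 fell with TGFβ, 2317 in all. XYLT1 (2.86, SE 0.11, adjusted p 5.12e-08), ACTA2 (2.32, SE 0.10, 8.11e-08), BHLHE40 (2.25), NUAK1 (2.36) and the cytokine IL11 (1.91) rose in each of the 4 pairs. NTN4 (-1.66), COLEC12 (-1.99), the matrix protein MXRA5 (-1.27), SLC7A14 (-1.90) and CCN3 (-2.13) fell in each. The count was 263 without pairing by background, 62 with the background subtracted and 0 by ordinary least squares, with 4084 genes at an unadjusted p under 0.05. It was 1331 and 1330 without the DMSO arrays (without and with TGFβ), 1438 and 1430 without those of C646, and 1247 and 1234 without those of control shRNA.

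The TGFβ response was smaller in p300 shRNA cells. 266 genes differed 2-fold with TGFβ in control shRNA cells (171 higher, 95 lower) and 110 in p300 shRNA cells (70 and 40). The DMSO pair had 277 (156 and 121) and the C646 pair 189 (129 and 60). Genes differed in this: ACTA2 responded by 2.42 in control shRNA and 2.34 in p300 shRNA cells, and by 2.55 in DMSO and 1.95 in C646 cells. The median response of the contractile list was 0.77 and 0.66 in the shRNA arm and 0.71 and 0.72 in the inhibitor arm, and that of collagens and matrix proteins 0.40 and 0.34, and 0.36 and 0.47. The TGFβ response of CNN1 was 2.25 in control shRNA and 1.24 in p300 shRNA cells, and 2.36 in DMSO and 0.97 in C646 cells. That of ACTG2 was 3.33 and 1.92, and 3.10 and 1.61. PDGFD responded by -2.09 and -0.43, and by -2.09 and -0.998. CNN1, ACTG2 and PDGFD were among the top genes of the control pairs, so selection on the same arrays can enlarge these gaps. ID1 differed between the arms: with TGFβ it was higher by 3.52 in control shRNA and at -0.01 in p300 shRNA cells, and higher by 1.95 in DMSO and 2.52 in C646 cells.

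The 156 genes that were 2-fold higher with TGFβ in DMSO cells, a selection that shares no array with the shRNA arm, had a median TGFβ response of 1.28 in control shRNA cells and 0.72 in p300 shRNA cells. With TGFβ these genes had a median difference of -0.36 between p300 shRNA and control shRNA cells, 116 of the 156 below 0, against -0.04 to 0.07 for matched random lists. Without TGFβ the difference was 0.15. The 121 genes lower with TGFβ in DMSO cells responded by -1.02 and -0.59, and differed by -0.03 with and -0.36 without TGFβ. In the other direction, the 171 genes higher with TGFβ in control shRNA cells responded by 1.18 in DMSO and 1.08 in C646 cells and differed by -0.05 between C646 and DMSO with TGFβ, and by -0.03 without it. The 95 lower genes responded by -1.22 and -0.91 and were higher with C646 in the presence of TGFβ by a median of 0.23, 78 of 95 above 0, and by -0.01 without TGFβ. No p-value goes with these medians. The -0.36 was -0.18 with the background subtracted and -0.20 with selection at 1.5-fold, and the -0.05 was -0.11 to -0.14 under 5 alternatives.

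Tested gene by gene across both arms, the interaction of p300 loss with TGFβ gave 0 genes by limma, with 858 genes at an unadjusted p under 0.05 and 0 by ordinary least squares. ACTG2 had an interaction of -1.45, CNN1 of -1.20 and PDGFD of 1.38. As a list, the TGFβ and SMAD targets had a median interaction of -0.36 (camera adjusted p 1.72e-08, adjusted p = 0.718 with an estimated correlation; 0 and 1 called adjusted over the list alone). Contractile genes (median -0.10, camera adjusted p 0.000763), matrix enzymes (-0.17, 0.000976), collagens (-0.10, 0.0353), cell cycle (-0.12, 0.000103) and interferon-stimulated genes (-0.17, 0.00191) were lower too, each with adjusted p = 0.718 with an estimated correlation. The count was 10 without the C646 array, 10 without C646 + TGFβ, 1 without either control shRNA array and 2 without either p300 shRNA array.

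In TGFβ-treated cells the genes lower with both C646 and p300 shRNA included some of the most strongly induced ones. The TGFβ-treated control arrays enter both comparisons. A gene that reads too high on them therefore looks both induced and lower with p300 loss. KANK4 was lower by -1.31 with C646 and -2.05 with p300 shRNA, CNN1 by -1.66 and -1.14, the fatty acid binding protein FABP3 by -1.48 and -1.08, and CDKN2B, the cell cycle inhibitor p15, by -0.92 and -0.94. PRUNE2 (-1.08 and -1.56), the cholesterol enzyme DHCR7 (-1.06 and -1.78), the acetyl-CoA synthetase ACSS2 (-0.99 and -1.51), the calcium channel CACNA1H (-1.11 and -0.94), HMOX1 (-0.91 and -1.02) and the protease inhibitor TIMP3 (-1.18 and -0.90) were lower in both arms as well. Higher in both were EDN1, the vasoconstrictor endothelin (1.20 and 1.47), RGCC (1.30 and 1.27), the immediate early gene EGR1 (1.37 and 1.18), the collagen receptor integrin ITGA2 (1.10 and 1.28), TMEM158 (0.99 and 1.91), adrenomedullin (ADM, 0.91 and 0.89), EPDR1 (0.83 and 0.96), PHLDA1 (0.80 and 1.74), the ERK phosphatase DUSP5 (0.78 and 1.04) and RIN2 (0.77 and 1.25).

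None of these passed the test across arms. limma called 0 genes for p300 loss with TGFβ, and 942 had an unadjusted p under 0.05 where chance gives 745. Ordinary least squares called 0 here as in every fit, which adds no evidence. The lowest adjusted p was 0.124, shared by RGCC, EDN1, ITGA2, ADM, KANK4, CNN1 and PRUNE2. Across genes the C646 and p300 shRNA effects had r = 0.15 and rho = 0.10, and genes are not independent replicates. 4 genes were 2-fold higher and 5 lower in both arms, and 1 went opposite ways. Leaving out 1 array gave 25 genes without DMSO, 24 without C646, 22 without control shRNA, 21 without p300 shRNA, 9 without DMSO + TGFβ or without C646 + TGFβ, 3 without control shRNA + TGFβ and 2 without p300 shRNA + TGFβ. It was 4 without a filter and 2 with the background subtracted.

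**Figure D3:**
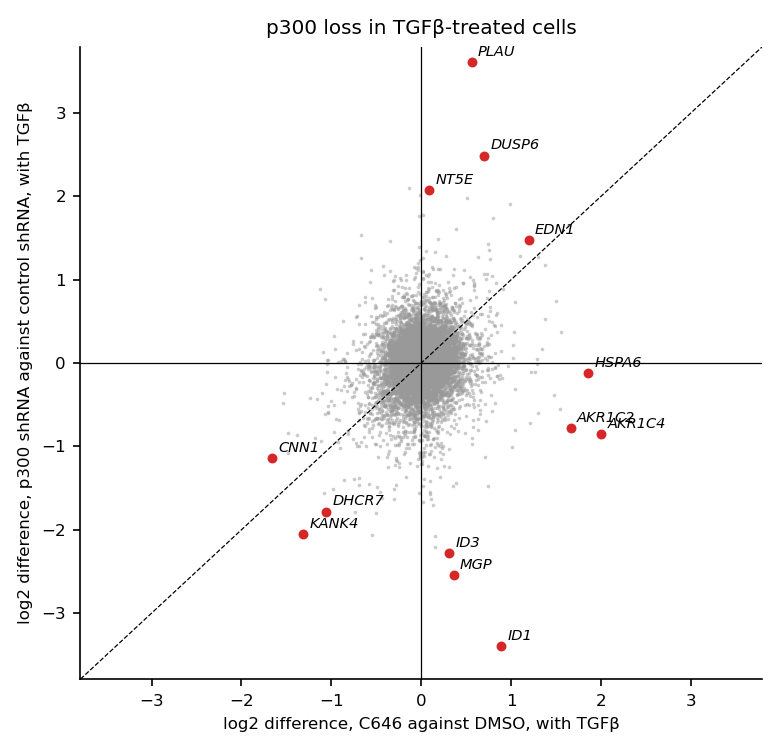
Log2 difference in TGFβ-treated cells for C646 against DMSO (horizontal) and p300 shRNA against control shRNA (vertical), 1 point per gene for 14896 genes, with named genes in red and equality dashed. KANK4 and CNN1 are low in both, while PLAU (0.56 and 3.61) and HSPA6 (1.86 and -0.12) differ in 1 arm.

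By list, contractile genes had a median of -0.25 with p300 loss under TGFβ (camera adjusted p 3.34e-09, adjusted p = 0.383 with an estimated correlation), and 5 of 24 were lower adjusted over the list alone; CNN1, ACTG2 (-1.49 and -0.83) and the myosin light chain MYL9 (-0.71 and -0.99) had the largest differences. Collagens and matrix proteins had a median of -0.24 (camera adjusted p 7.42e-07, adjusted p = 0.383 with an estimated correlation; 5 of 32 lower adjusted over the list alone), with COL16A1 (-0.69 and -0.99), SPARC (-0.76 and -0.91) and fibrillin (FBN1, -0.52 and -0.97). TGFβ and SMAD targets had a median of -0.25 (camera adjusted p 7.42e-07, adjusted p = 0.383 with an estimated correlation; 2 of 27 lower adjusted over the list alone), with LRRC32, which presents latent TGFβ, at -0.69 and -1.47. ID1 went apart in the arms, at 0.89 with C646 and -3.40 with p300 shRNA, and ID3 at 0.31 and -2.28. Cholesterol synthesis genes had a median of -0.33 (camera adjusted p 2.28e-07, adjusted p = 0.383 with an estimated correlation; 3 of 17 lower adjusted over the list alone).

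Amino acid and endoplasmic reticulum stress genes (median -0.20, camera adjusted p 0.00442, adjusted p = 0.636 with an estimated correlation), matrix enzymes (-0.14, 0.00267, 0.636 with an estimated correlation) and growth factors (-0.11, 0.0285, 0.383 with an estimated correlation) were lower by less. With C646 and p300 shRNA their medians were -0.25 and -0.04, -0.24 and -0.11, and -0.01 and -0.12. Interferon-stimulated genes were lower (-0.17, camera adjusted p 9.81e-05, adjusted p = 0.707 with an estimated correlation), with a median of -0.56 in the shRNA and 0.10 in the inhibitor arm; in the shRNA arm their level is far above that of the inhibitor arm (median log2 difference 2.71 between the TGFβ-treated controls). Inflammatory genes were higher (0.21, camera adjusted p 0.00569, adjusted p = 0.383 with an estimated correlation; 1 higher and 1 lower adjusted over the list alone), with a median of 0.00 with C646 and 0.25 with p300 shRNA; CXCL8 was at 1.497 and 0.74 and CXCL1 at 0.70 and 1.06, and this list, too, has a higher level in the shRNA arm (0.82). Cell cycle genes went opposite ways in the arms, with a median of -0.15 with C646 (24 of 29 below 0) and 0.32 with p300 shRNA (28 above 0), so their median of 0.10 over both (camera adjusted p 0.0338, adjusted p = 0.8 with an estimated correlation) describes neither.

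Without TGFβ, cholesterol synthesis genes were lower as a list with p300 loss (median -0.40, camera adjusted p 4.01e-10, adjusted p = 0.613 with an estimated correlation; 6 of 17 lower adjusted over the list alone), with DHCR7 at -0.90 with C646 and -2.10 with p300 shRNA, the mevalonate enzyme MVD at -1.13 and -0.96, and FDPS at -0.99 and -0.85. Cell cycle genes had a median of 0.22 (camera adjusted p 3.49e-07, adjusted p = 0.706 with an estimated correlation; 1 higher adjusted over the list alone), which came from the shRNA arm: it was 0.01 with C646 (15 of 29 above 0) and 0.44 with p300 shRNA (29 above 0). MCM4 (0.66 and 0.70) and TYMS (0.53 and 0.78) were higher in both arms, TOP2A (0.01 and 1.45) and UBE2C (-0.24 and 1.58) in the shRNA arm alone. Inflammatory genes had 0.27 (camera adjusted p 0.00779, adjusted p = 0.613 with an estimated correlation), again from the shRNA arm, with -0.01 with C646 and 0.39 with p300 shRNA, and from a higher level there (1.61). CCL2 (0.93 and 0.52) was higher in both arms, CXCL5 (-0.05 and 1.42) and CCL7 (0.26 and 2.17) mostly with p300 shRNA, and VCAM1 (-0.33 and -1.55) was lower. Collagens had -0.13 (camera adjusted p 0.0153, adjusted p = 0.613 with an estimated correlation). limma called 0 genes, with 1038 at an unadjusted p under 0.05 and 0 by ordinary least squares, and the r across genes between the arms was 0.128. The count was 71 without DMSO, 65 without C646, 5 without DMSO + TGFβ, 3 without C646 + TGFβ, 2 without control shRNA + TGFβ, 3 without p300 shRNA + TGFβ, and 1 without a filter.

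Taking all 4 pairs of p300 loss as repeats, 5 genes passed. ITGA2, the collagen-binding integrin chain, rose 2.25-fold (log2 1.17, SE 0.10, adjusted p 0.00768), and the small noncoding RNA SNAR-A1 (0.85, adjusted p 0.0296) and the intracellular cation channel TMEM38B (0.82, 0.0314) rose. FABP3 fell by 1.57 on the log2 scale (SE 0.15, adjusted p 0.00949) and TSC22D3, a glucocorticoid-induced gene also known as GILZ, by 1.09 (0.0296). Each moved the same way in all 4 pairs. 2072 genes had an unadjusted p under 0.05 where chance gives 745. The count moved with nearly every choice. It was 28 with the values as deposited (8 higher, 20 lower), 23 with median centring (8 and 15) and 25 without a filter (9 and 16). It was 3 with the mean of probes, 1 with eBayes without trend, and 0 with the background subtracted, without pairing or by ordinary least squares. Without 1 array it was 0 (DMSO, C646), 2 (control shRNA + TGFβ), 3 (DMSO + TGFβ, C646 + TGFβ, p300 shRNA + TGFβ) or 10 (control shRNA, p300 shRNA).

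The effects of the arms were then estimated separately, each over its pairs without and with TGFβ, with 1 residual shared by both arms. This residual is the spread of an effect between the states without and with TGFβ. The C646 calls therefore depend on the shRNA arrays too. With C646, 5 of 15 NRF2 and oxidative stress genes rose and 5 of 17 cholesterol synthesis genes fell; for both lists camera gave adjusted p = 0.431 with an estimated correlation. The heat shock protein gene HSPA6 rose at least 3.53-fold (log2 1.82, SE 0.09, adjusted p 1.1e-06), from 115 in DMSO and 100 in DMSO + TGFβ cells, near the array medians of 109 and 111. The NRF2-linked reductase PTGR1 rose 3.10-fold (1.63, SE 0.13, 0.00018) and the lysosomal galactosidase GLA 2.82-fold (1.497, SE 0.14, 0.000419). PYCR1, the last enzyme of proline synthesis (-1.31, SE 0.13, adjusted p 0.000499), the collagen chaperone SERPINH1 (-1.09), FABP3 (-1.57), TIMP3 (-1.23) and CBS, an enzyme of the cysteine pathway (-1.01), fell, and the chemokine CCL26 (1.05, from near the background) and TIPARP, a target of the aryl hydrocarbon receptor (1.27), rose. Each moved the same way in both pairs.

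In the single pairs, AKR1C4, of the aldo-keto reductase family, differed by 1.62 without and 2.01 with TGFβ, AKR1C2 by 1.66 with TGFβ, CEMIP by 1.54 with TGFβ and the linker histone gene H1-2 by 1.35 without it. COL15A1 (-1.58) and SLIT3 (-1.33) were lower without TGFβ, TMEM97 in both (-1.51 and -1.52), and ACTG2 (-1.49) and the cardiac actin ACTC1 (-1.54) with it; without TGFβ, ACTG2 was at 0.00 and ACTC1 at 0.11. By limma 116 genes rose and 85 fell with C646, 201 in all, with 1962 at an unadjusted p under 0.05. The count was 88 with the mean of probes and 0 with the background subtracted or by ordinary least squares. It was 33 without DMSO, 22 without DMSO + TGFβ, 48 without C646 and 22 without C646 + TGFβ, and 730, 719, 728 and 727 without control shRNA, control shRNA + TGFβ, p300 shRNA and p300 shRNA + TGFβ.

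Of 17 cholesterol synthesis genes 5 fell with C646 and none rose (12 and 0 adjusted over the list alone), with MVD (-1.08), FDPS (-1.05), DHCR7 (-0.98) and ACAT2 (-0.76). In the amino acid and endoplasmic reticulum stress list 6 of 22 fell (10 adjusted over the list alone), among them TRIB3 (-0.93), the chaperone HSPA5 (-0.85) and the serine synthesis enzyme PSAT1 (-0.79), while the cystine transporter SLC7A11 rose (0.68). 4 of 32 collagens and matrix proteins fell (6 adjusted over the list alone): SPARC (-0.88), periostin (POSTN, -0.65), COL16A1 (-0.63) and COL5A1 (-0.58). TIMP3 and SERPINH1 were the 2 of 24 matrix enzymes that fell (1 up and 9 down adjusted over the list alone). Contractile genes had no call over all genes, and 1 up and 5 down adjusted over the list alone. A C646 effect that differs with TGFβ counts as spread in this fit, as for CNN1 (-0.27 without and -1.66 with TGFβ) and ACTG2 (0.00 and -1.49). Camera adjusted p for these lists was 1.63e-13, 3.91e-08, 4.37e-06, 8.17e-06 and 3.13e-05, and each had adjusted p = 0.431 with an estimated correlation.

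Of 15 NRF2 and oxidative stress genes 5 rose with C646 (7 up and 1 down adjusted over the list alone), with AKR1C2 (1.501), the sulfiredoxin SRXN1 (0.74), AKR1B10 (0.68) and PGD (0.59). Of 27 interferon-stimulated genes MX1 (0.74), IFIT1 (0.67) and ISG15 (0.64) rose (8 up adjusted over the list alone), and of 14 heat shock genes CRYAB rose (0.74; 5 up and 1 down adjusted over the list alone). Camera adjusted p was 8.6e-05, 0.000189 and 0.00791, and each had adjusted p = 0.431 with an estimated correlation. Calls in other lists were CDKN1A, the p53 target p21 (0.65), CCL2 (0.79) and SOD2 (0.96) of the inflammatory list, the neurotrophin receptor NGFR (0.48) of the quiescent list, WNT2 (-0.45) and CCDC80 (-0.69). Of 9 leukocyte markers 1 rose beside the interferon-stimulated genes, CD68 (0.62, adjusted p 0.0394). Cell cycle genes had no call and a median of -0.09 (camera adjusted p 0.0298, adjusted p = 0.621 with an estimated correlation).

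The p300 hairpin went with a larger and different set of changes. PLAU, the urokinase plasminogen activator, rose 9.58-fold (log2 3.26, SE 0.17, adjusted p 1.43e-06), the ERK phosphatase DUSP6 6.76-fold (2.76, SE 0.16, 1.73e-06), the phosphate transporter SLC20A1 4.55-fold (2.19), the ectonucleotidase NT5E 4.05-fold (2.02) and ANGPTL4, a lipoprotein lipase inhibitor, at least 3.75-fold (1.91), from log2 levels of 6.79 and 6.94 near the background. MGP, an inhibitor of calcification (-2.54, SE 0.16, adjusted p 3.43e-06), TMEM119 (-2.10), DHCR7 (-1.94), RTN3 (-1.82) and the homeobox factor MKX (-1.59) fell, and all of these moved the same way in both pairs. Single-pair differences were large for STC1 (2.30 without and 2.10 with TGFβ), the chemokine CCL7 (2.17 without), ACSS2 (-2.71), ADH1A (-2.63), PDGFD (-2.42) and AKR1C2 (-2.18) without TGFβ, and for ID1 (-3.40), ID3 (-2.28) and LMCD1 (-2.08) with it; ID1 was at 0.13 without TGFβ.

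By limma 795 genes rose and 841 fell, 1636 in all, with 3629 at an unadjusted p under 0.05. The count was 1 with the background subtracted and 0 by ordinary least squares.

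With p300 shRNA 18 of 29 cell cycle genes rose, and 24 adjusted over the list alone (camera adjusted p 1.93e-15, adjusted p = 0.439 with an estimated correlation): UBE2C (1.42), AURKA (1.21), TOP2A (1.004) and GINS2 (0.82), which serve mitosis and DNA replication. The list stands lower in control shRNA than in DMSO cells, by a median of -0.29 without and -0.47 with TGFβ. Of 27 interferon-stimulated genes 14 fell, and 21 adjusted over the list alone (camera adjusted p 4.42e-14, adjusted p = 0.439 with an estimated correlation): IFIT2 (-1.37), RSAD2 (-1.14), OAS2 (-0.98) and the RNA sensor IFIH1 (-0.96). Of 9 leukocyte markers CD68 (-0.63) and CD74 (-0.33) fell beside them. The interferon-stimulated genes called fell from a level in control shRNA cells that is above that of DMSO cells by a median log2 difference of 2.29. Of 20 inflammatory genes 9 rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p 1.6e-05, adjusted p = 0.406 with an estimated correlation), with the chemokines CCL7 (1.78), CXCL5 (1.25), CCL20 (1.04) and CXCL8 (1.01), from a control level 1.61 above that of DMSO cells.

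9 of 17 cholesterol synthesis genes fell and none rose (10 and 0 adjusted over the list alone; camera adjusted p 1.6e-05, adjusted p = 0.566 with an estimated correlation), with DHCR7, LSS (-0.99), MVD (-0.74) and EBP (-0.61), and SREBF1, a regulator of lipid synthesis held in the quiescent list, fell (-1.11). 6 of 15 NRF2 and oxidative stress genes fell (7 adjusted over the list alone; camera adjusted p 1.6e-05, adjusted p = 0.406 with an estimated correlation): AKR1C3 (-1.77), AKR1C2 (-1.48), PIR (-0.75) and HMOX1 (-0.74). 5 of 24 contractile genes fell, over all genes and adjusted over the list alone (camera adjusted p 0.00197, adjusted p = 0.522 with an estimated correlation), with MYL9 (-0.91) and its kinase MYLK (-0.85). Collagens and matrix proteins had 7 of 32 lower and 1 higher (12 and 3 adjusted over the list alone; camera adjusted p 0.0138, adjusted p = 0.515 with an estimated correlation), with COL16A1 (-0.97), FBN1 (-0.70) and SPARC (-0.62) against thrombospondin (THBS1, 1.40 without and 0.35 with TGFβ).

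TGFβ and SMAD targets went both ways with p300 shRNA, 2 up and 5 down of 27 (3 and 11 adjusted over the list alone; camera adjusted p 0.0199, adjusted p = 0.711 with an estimated correlation), with ANGPTL4 up and ID3 (-0.33 without and -2.28 with TGFβ), LRRC32 (-0.46 and -1.47) and RASL12 (-0.46 and -1.20) down. The median of this list was 0.04 without and -0.41 with TGFβ. YAP and TAZ targets went both ways too, 6 up and 3 down of 22 (9 and 4 adjusted over the list alone; camera adjusted p 0.033, adjusted p = 0.566 with an estimated correlation), with NT5E, ANKRD1 (0.40 without and 1.60 with TGFβ), FJX1 (0.99) and CCN1 (0.91) up; their median was 0.34 without and -0.09 with TGFβ. Of 24 matrix enzymes 4 rose, among them the collagenase MMP1 (1.49) and the stromelysin MMP3 (0.82), and 4 fell, among them the protease inhibitor TIMP3 (-0.61), with a median of 0.01 (camera adjusted p 0.736, adjusted p = 0.875 with an estimated correlation). Of 23 growth factors 4 fell, among them PDGFD (-2.42 without and -0.76 with TGFβ), the BMP antagonist GREM1 (-1.20) and ANGPT1 (-0.59), and LIF (0.88) rose. In the amino acid and endoplasmic reticulum stress list STC2 (-0.99), ATF3 (-0.28 without and -1.18 with TGFβ) and ATF4 (-0.44) fell, with a list median of 0.11 and a mean of 0.00. CRYAB (-0.996), which rose with C646, fell with p300 shRNA.

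**Figure D4:**
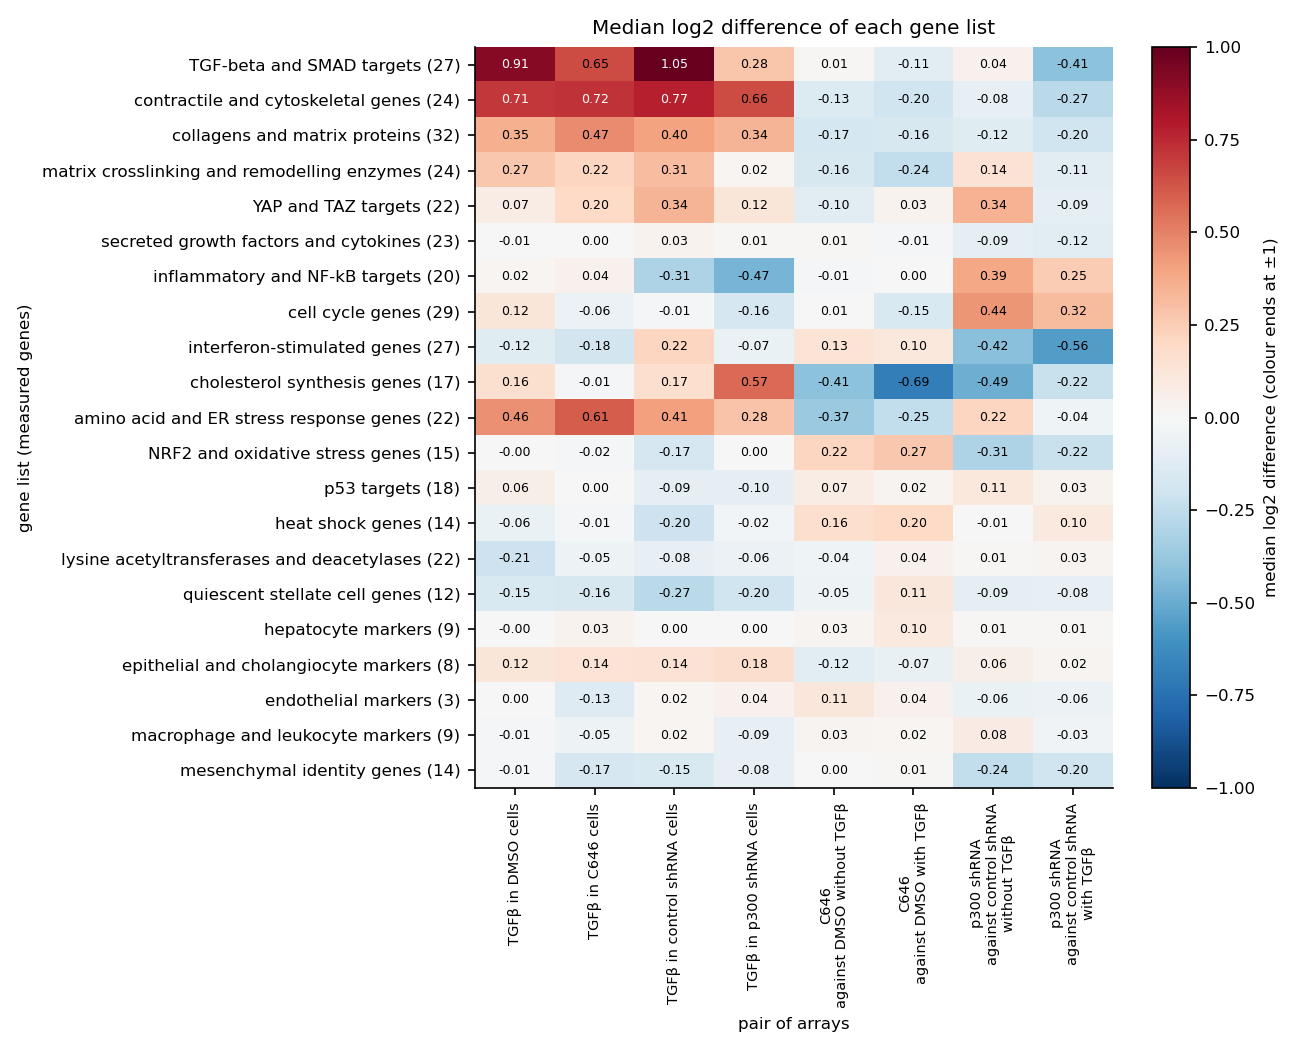
Median log2 difference (colour and printed value, colour ending at 1 in each direction) of 21 gene lists (vertical axis, with the number of measured genes) in 8 pairs of arrays (horizontal axis). The interferon-stimulated list has -0.42 and -0.56 in the p300 shRNA pairs against 0.13 and 0.10 in the C646 pairs, and the TGFβ and SMAD targets respond to TGFβ by 1.05 in control shRNA and 0.28 in p300 shRNA cells.

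The difference between the effects of p300 shRNA and C646 was itself tested, and 666 genes passed by limma, 314 with the higher value under p300 shRNA and 352 with the lower, with 2737 at an unadjusted p under 0.05. PLAU (2.89, SE 0.23, adjusted p 9.55e-05), SLC20A1 (2.20), NT5E (2.05) and the cyclin CCND1 (2.01) were on one side, and AKR1C4 (-3.24, SE 0.30, adjusted p 0.00016), MGP (-2.51), TMEM119 (-2.15) and ID2 (-1.89) on the other. Cell cycle genes (13 of 29 higher, median 0.45, camera adjusted p 2.55e-15), interferon-stimulated genes (13 of 27 lower, -0.64, 9.61e-17) and NRF2 genes (5 of 15 lower, -0.51, 5.08e-10) differed between the arms as lists, each with adjusted p = 0.368 with an estimated correlation. So did 4 more, all higher with p300 shRNA: inflammatory genes (5 of 20 higher and 1 lower, median 0.24, camera adjusted p 0.00352, adjusted p = 0.368 with an estimated correlation), matrix enzymes (4 of 24 higher, 0.30, camera adjusted p 0.000368, adjusted p = 0.477 with an estimated correlation), amino acid and endoplasmic reticulum stress genes (3 of 22 higher, 0.39, camera adjusted p 0.00103, adjusted p = 0.477 with an estimated correlation) and YAP and TAZ targets (3 of 22 higher and 1 lower, 0.29, camera adjusted p 0.00623, adjusted p = 0.588 with an estimated correlation). Of 17 cholesterol synthesis genes 5 fell with C646 and 9 with p300 shRNA (adjusted p = 0.431 and adjusted p = 0.566 with an estimated correlation), and the difference of the effects had a median of 0.10 (camera adjusted p 0.506). The count was 210 without DMSO, 157 without DMSO + TGFβ, 207 without C646, 158 without C646 + TGFβ, 1236 without control shRNA + TGFβ and 1253 without p300 shRNA + TGFβ, 1 with the background subtracted and 0 by ordinary least squares.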

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

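The comparison of the arms, the test of other splits and the tests of the 3 patterns below were chosen after the results were seen, except the tests of intensity distributions and of AKR1C probes, whose outcomes had not been looked at when they were set up.

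The effects of p300 shRNA and C646 differed for 666 genes, a difference between groups found by limma (p300 shRNA effect minus C646 effect, log2). Among the named genes it was 2.89 for PLAU, 2.31 for DUSP6, 2.20 for SLC20A1, 2.05 for NT5E, 2.04 for STC1, 1.66 for CCL7, 1.07 for RIN2, 1.06 for PYCR1 and 0.98 for TMEM158. It was -3.24 for AKR1C4, -2.98 for AKR1C2, -2.51 for MGP, -2.15 for TMEM119, -1.89 for HSPA6, -1.85 for CEMIP, -1.80 for ID3, -1.55 for GLA, -1.55 for H1-2, -1.44 for PTGR1, -1.35 for ACSS2, -1.28 for LMCD1 and -0.96 for DHCR7. HSPA6 reads near the background in all arrays but those with C646, so its value is not exact. The adjusted p of these genes ran from 4.32e-05 (HSPA6) to 0.0417 (LMCD1). For AKR1C2 and AKR1C4 the effects had opposite signs, 1.501 and 1.81 with C646 against -1.48 and -1.43 with p300 shRNA, and for DHCR7 they had the same sign, -0.98 and -1.94. The count was 210 without DMSO, 157 without DMSO + TGFβ, 207 without C646, 158 without C646 + TGFβ, 1236 without control shRNA + TGFβ and 1253 without p300 shRNA + TGFβ.

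Probes with no gene symbol, which the gene analysis leaves out, also answered to TGFβ: 452 of 9352 were called over the 4 backgrounds (231 higher, 221 lower), and 12 were 2-fold higher and 9 lower in both control backgrounds.

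Other splits of the 8 arrays into 4 and 4 were fitted with the same blocks, and 32 of 35 could be fitted. For TGFβ over 4 backgrounds only the real split, 1 of 32, gave as many as its 2317 genes, and the highest other gave 3. The other splits leave the TGFβ effect in their residuals, which can lower their counts. Only 8 splits part every pair as the real one does, too few for a share under 0.05, and the highest other of these gave 0. For p300 loss 3 of 32 splits, the real one included, gave at least its 5 genes, and the highest other gave 832. The splits with 832 genes part p300 shRNA from control shRNA arrays, and their blocks take up the inhibitor arrays. These genes therefore come from the shRNA pairs alone. They point to a structure of the samples, a difference between p300 shRNA and control shRNA cells. These splits cannot tell the hairpin from a difference of culture, cell passage or transduction, which is confounded with it. Such splits are no measure of chance, and whether chance can be excluded for the 5 genes stays open.

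One pattern is the smaller TGFβ response of p300 shRNA cells. Over the 156 genes 2-fold higher with TGFβ in DMSO cells, the response in p300 shRNA minus control shRNA cells had a median of -0.52, on arrays that took no part in the selection, which argues against selection as its source. Under 4 scalings its highest value was -0.475, which argues against different intensity distributions. A higher baseline is not the whole gap, since with TGFβ alone the median was -0.36. A candidate explanation, not tested here, is that p300 adds to the induction of these genes. For induced genes the inhibitor arm shows less of the pattern. The 171 genes higher with TGFβ in control shRNA cells responded by a median of 1.18 in DMSO and 1.08 in C646 cells. With TGFβ they differed by -0.05 between C646 and DMSO, just below random lists (-0.04 to 0.04), and by -0.11 to -0.14 under some alternatives. The 95 genes lower with TGFβ in control shRNA cells responded by -1.22 in DMSO and -0.91 in C646 cells. For these lowered genes the response was thus smaller with C646 as well. A difference of culture, cell passage or transduction between the 2 shRNA lines is confounded with the hairpin and stays open.

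Another is the level of interferon-stimulated and inflammatory genes in the shRNA arm. A large share of leukocytes in these cultures is argued against by the leukocyte markers: their median difference from the inhibitor arm was at most 0.068 over 4 matched pairs and inside the range of random lists in each. A small share could go unseen, since the median of 9 markers, some near the background, would move little. CD68, the brightest of these markers, had a log2 level of 9.92 in control shRNA and 9.31 in DMSO cells, and PTPRC, which marks all leukocytes, 6.70 and 6.69, near the background. A response to the shRNA vector may underlie it, yet that cannot be told apart from another difference between the arms, since the arm has no untreated cells: the lowest of the 4 medians of the interferon-stimulated list was 1.78. The decrease of that list with p300 shRNA was measured on top of this level.

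The last is the median of the NRF2 list, higher with C646 and lower with p300 shRNA. Members went both ways with C646: with TGFβ, AKR1C2 was at 1.66, GCLM at -0.20 and HMOX1 at -0.91. HMOX1 was also lower with p300 shRNA, at -1.02. Probes that read several AKR1C transcripts are argued against as the source of the list's median. The 13 genes left without AKR1C genes had a median difference between the arms of -0.49, against -0.20 to 0.19 for random lists. With all 15 genes it was -0.51, and a median moves little when so few are dropped. Whether shared probes produce the AKR1C2 and AKR1C4 values themselves was not tested. An effect of C646 apart from p300 stays open: the heat shock list was also above random lists with C646 (0.16 without and 0.20 with TGFβ), but this was set up after the results were seen and the NRF2 list is the pattern itself, so neither tests it. The decrease with p300 shRNA (-0.31 and -0.22), the small EP300 difference, which did not pass the test, and the dose of C646 stay open as well.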

How the results depend on the processing

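The alternative that subtracts the background, and TGFβ as an additive term, were chosen after seeing the data, and the tests of the other alternatives were planned. No value of a named gene changed direction under the other scalings, filters and models (2551 on the main side of the threshold, 548 weaker, 10 stronger); of 2488 values with 1 array left out, 34 reversed, 283 were weaker and 145 stronger. Of the list calls 290 held and 62 were weaker, 44 of these with an estimated correlation, which ends every list call. With that setting camera tests on the 2 residual degrees of freedom of these fits. Its p-values can hardly pass for any list, so they do not tell the lists apart. The p-values with the preset correlation rest on the assumed value of 0.01. With 1 array per group, leaving out an array takes its pair out of the contrast. Ordinary least squares, with 2 or 3 residual degrees of freedom, called 0 genes in every fit, so its counts do not tell the results apart. No paired analysis by donor was possible because the labels name no donor. Dim genes near the background limit what can be seen. Counts with the background subtracted are over 19951 genes, not 14896, so they join the subtraction with the loss of the filter. Where a count below moved, the cause was not tested.

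Genes changed by TGFβ over 4 backgrounds were 62 with the background subtracted, 263 without pairing and 0 by ordinary least squares, and 1234 to 2442 without 1 array. In controls they were 1, 447 with the arm as the only block, 0 by ordinary least squares, and 530 to 1926 without 1 array. For p300 loss over 4 pairs the counts were 28 as deposited (8 higher, 20 lower against 3 and 2), 23 with median centring (8 and 15), 25 without a filter (9 and 16), 3 with the mean of probes, 1 with eBayes without trend, 0 with the background subtracted, without pairing or by ordinary least squares, and 0 to 10 without 1 array. With TGFβ they were 4 without a filter, 2 with the background subtracted and 2 to 25 without 1 array; without TGFβ 1 without a filter and 0 to 71; the interaction 0 to 10.

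C646 gave 88 genes with the mean of probes, 0 with the background subtracted or by ordinary least squares and 22 to 730 without 1 array. p300 shRNA gave 1 and 0, and the difference of the arms 1 and 0, with 157 to 1253 without 1 array. p300 shRNA gave 1129 to 1602 genes without 1 array.

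Genes 2-fold apart with TGFβ in DMSO, C646, control shRNA and p300 shRNA cells numbered 1160, 814, 965 and 535 with the background subtracted, and 960, 640, 840 and 468 at 1.5-fold. For C646 without and with TGFβ they numbered 376 and 478 with the background subtracted, 273 and 310 at 1.5-fold and 22 and 35 with 50 added, and 34 with TGFβ with the mean of probes. For p300 shRNA they numbered 1140 and 915, and 1020 and 770. A lower threshold holds more genes by construction.

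For the DMSO-induced genes the p300 shRNA difference with TGFβ was -0.18 with the background subtracted and -0.20 with selection at 1.5-fold. For the genes induced in control shRNA cells the C646 difference with TGFβ was -0.11 as deposited, -0.11 with median centring, -0.14 with the background subtracted, -0.14 with selection at 1.5-fold and -0.14 for the 100 most changed genes.

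Leaving out 1 array reversed these log2 values, most between the arms. TGFβ in controls: TNFAIP6 -0.073 to 2.56, CXCL10 -0.12 to 1.25. C646: ACTC1 -1.54 to 0.11, ACTG2 -1.49 to 0.0033. p300 shRNA: ID1 -3.40 to 0.13. p300 loss without TGFβ: CXCL5 -0.046 to 1.42, UBE2C -0.24 to 1.58. p300 loss with TGFβ: AURKA -0.43 to 1.17, CCL7 -0.023 to 1.40, CXCL10 -1.42 to 0.10, GREM1 -0.99 to 0.24, ID1 -3.40 to 0.89, ID3 -2.28 to 0.31, IFIT2 -1.63 to 0.11, MCM6 -0.15 to 0.76, RSAD2 -1.57 to 0.10 and UBE2C -0.67 to 1.26.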

Other observations

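The tests of the histone, ERK and hypoxia hypotheses were set up before the genes they measure had been looked at, though the hypotheses themselves came from other genes of these arrays.

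The shRNA arm stands apart from the inhibitor arm in its interferon and chemokine genes. In control shRNA against DMSO cells without TGFβ, all 27 measured interferon-stimulated genes were higher, 24 of them at least 2-fold. Examples chosen after their values were seen are MX1, with a log2 level of 12.53 in control shRNA and 7.55 in DMSO cells, IFIT1 (11.99 and 7.88) and IFI44L (10.78 and 6.90). The median difference of the list was 2.29 without and 2.71 with TGFβ between the controls, and 1.78 and 1.87 between p300 shRNA and C646 cells. The inflammatory list followed, with medians of 1.61, 0.82, 1.98 and 1.49; the neutrophil chemokine CXCL8 had a level of 13.01 in control shRNA and 7.77 in DMSO cells, and IL6 11.13 and 7.27. These differences set 1 array against 1 array and have no test.

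Cell cycle genes went the other way between the controls. 26 of 29 were lower in control shRNA than in DMSO cells without TGFβ (median -0.29) and 27 of 29 with it (-0.47), while p300 shRNA against C646 cells had a median of 0.12 without TGFβ and, inside the range of random lists, 0.05 with it. Cholesterol synthesis genes were lower in control shRNA than in DMSO cells (-0.29 without and -0.31 with TGFβ), and p53 targets higher (0.24 and 0.16). Markers of hepatocytes (-0.01 and 0.02) and mesenchymal identity genes (0.00 and 0.02) differed little between these controls.

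DUSP6, SPRY4 and their kin are induced by the ERK kinases, and the rise of DUSP6 with p300 shRNA led to the hypothesis that ERK pathway output may be higher in these cells. 10 ERK pathway genes not looked at before had a median difference of 0.43 without TGFβ and 0.43 with it, above the ranges of matched random lists (-0.19 to 0.19 and -0.16 to 0.18). SPRY4 (1.24 without and 1.29 with TGFβ) and SPRED1 (0.96 and 1.33) had the largest differences, while EPHA4 (-0.23 and -0.05) and, with TGFβ, DUSP4 (0.14 and -0.17) were below 0. The result goes with the hypothesis; ERK activity itself was not measured, and a difference between cultures stays open.

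ANGPTL4 and STC1, which hypoxia can induce, were higher with p300 shRNA, and a hypoxia-type expression state might be the source. 15 other hypoxia genes had a median of 0.70 without TGFβ, above random lists (-0.19 to 0.15), but of 0.10 with TGFβ, inside them (-0.15 to 0.16). HK2 was higher in both (1.63 and 1.23), while SLC2A1 was at 1.13 without and -0.26 with TGFβ. The prediction asked for both states, so the hypothesis was not borne out for TGFβ-treated cells.

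H1-2 was higher with C646 (1.35 without and 1.22 with TGFβ), and a shared rise of histone transcripts might be the source. 34 other histone genes had a median of 0.05 without and 0.018 with TGFβ, inside the ranges of random lists (-0.05 to 0.06 in both), so the prediction was not borne out. Members went both ways, with H2BC5 at 0.62 and 0.42 and H2AC6 at -0.46 and -0.46. The random range is narrower than that of the 32 collagens and matrix proteins (-0.09 to 0.10 without TGFβ). Genes of matched level thus differed little, and a compressed rise of the class could be missed.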
